A study of Mus musculus with 6 samples.

How the data were processed

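RNA sequencing of whole ovaries from mice at 9 days post partum was analysed in 6 libraries, 3 from wild-type (WT) mice and 3 from mice in which Srsf1 had been knocked out in granulosa cells (cKO). Groups and replicate numbers were taken from the sample labels. Nothing in the labels says that the replicates of a group came from separate animals, so the p-values measure only the spread among these samples, which may be technical.

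The values were FPKM (fragments per kilobase of gene length, scaled to the library) per gene, as deposited by the authors in a single table for all 6 libraries. Per the submitters' processing notes, HISAT2 2.0.5 was used and the builds mm10 and GRCm39 were named, without a role for either. The chromosome accessions in the deposited table are those of GRCm39, and all positions below are the table's own. The read counter, the annotation release, the strandedness of the libraries and the strain of the mice are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies, can therefore not be told apart with certainty.

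The product of FPKM and the table's gene length was a whole multiple of a single step in each library, for 100% of the values within 0.01 of a whole number. The authors' FPKM values thus gave back whole reads, with 16.8 to 18.7 M reads per library. The denominators that the steps imply matched median-of-ratios size factors times the geometric mean of the library totals, with a ratio of 1 in each library. Libraries had thus already been scaled to each other by the authors, and no further scaling was applied. Mitochondrially encoded genes took 1.67% to 2.32% of the recovered reads, and the 10 most abundant genes of each library took 3.63% to 4.63%.

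The comparison, the pseudocount, the filter, the gene lists, the rule for named genes and all but a pair of the alternatives were chosen before the data were examined. FPKM values were transformed to log2(FPKM + 1), a scale that understates the change of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 14714 of 47205, of which 12729 were protein coding. cKO was compared with WT by the moderated, two-sided test of limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the prior variance). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are cKO minus WT on this log2 scale, with the moderated standard error (SE), and group values are mean FPKM ± SD over 3 libraries.

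Gene lists were tested with camera (limma) at its preset correlation between genes of 0.01, adjusted over the lists, beside camera with a correlation estimated for each list and fry. Of 30 lists, 28 had at least 3 tested members. For the 13 mitochondrially encoded genes the table's own symbols were used. A list's score in a library is the mean over its genes of log2(FPKM + 1) minus the WT mean, and the SE of its mean fold change is taken over libraries.

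Genes named are Srsf1 and Foxl2, then up to 10 on each side with the largest fold change among genes past the threshold whose groups do not overlap (genes without a symbol, predicted genes and pseudogenes left out), then up to 4 members of each described list with the smallest p-values. Where other genes are named, the text says that they were chosen after their values were seen.

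The gene test was tested on simulated data with the means of these libraries and with gene variances drawn from the prior that limma itself had fitted, over 14674 genes. That simulation replaced an earlier version with the same variance for every gene, in which more of the changed genes were called but the share of false calls was above the threshold. It called 64.3% of 98 genes changed 2-fold and 97% of 100 genes changed 4-fold, and 5 of its 165 calls were false. These shares depend on the many changed genes in the simulation, since the Benjamini-Hochberg cut is stricter where fewer genes are called. In the real data Srsf1 had an unadjusted limma p of 0.000185 but an adjusted p of 0.32. The shares are thus not the power reached in these libraries, and few calls do not show that few genes changed. In a like simulation over 14724 genes, camera at its preset correlation found a set of 20 genes moved 1.5-fold, and 1 of 100 unmoved sets passed the threshold before adjustment. Genes were simulated independently of each other there, so that the test does not cover lists whose genes vary together. Among the called lists, the estimated correlation was 0.936 for interferon, 0.659 for mitochondrially encoded and 0.509 for leukocyte genes.

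Alternatives were other pseudocounts (0.1 and 0.5), other filters (mean FPKM of 0.1 or 5, or none), values rescaled to a common total per library, equal medians, quantile normalization, a prior without a trend, a robust prior, library weights, the replicate number as a block, protein-coding genes only, and leaving out each library in turn. limma-voom on the recovered reads and a filter at 20 recovered reads were added after the data had been seen. Splicing was not analysed here, since the table holds a single value per gene. Figures were drawn with matplotlib 3.10.9.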

Results

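Whole mouse ovaries at 9 days post partum (dpp) were profiled by RNA sequencing, 3 libraries from WT mice and 3 from mice with Srsf1 knocked out in granulosa cells, the somatic cells that surround and nourish each oocyte. Srsf1 encodes a serine/arginine-rich splicing factor, and the comparison asks how its loss from granulosa cells alters gene expression in the ovary. The libraries held 16.8, 18.2 and 18.5 M recovered reads in WT and 18.6, 18.6 and 18.7 M in cKO. In libraries of this depth, 1 read in a gene of 1 kb corresponded to 0.052 to 0.0581 FPKM.

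Srsf1 (chromosome 11, 87937325 to 87944583, plus strand) was lower in every cKO library than in any WT library. It stood at 45.3 ± 4.96 FPKM in WT and 22.9 ± 3.52 FPKM in cKO (SD, n = 3 each), a log2 fold change of -0.96 (SE 0.134, limma adjusted p = 0.32). An exact two-sided permutation test of Srsf1 alone gave p = 0.1, the smallest that 3 against 3 libraries can give. Whole ovaries also hold oocytes, stroma and other cells besides granulosa cells, and the Cre driver is not given in the sources used here. Foxl2, the transcription factor that maintains granulosa cell identity (chromosome 9, 98837660 to 98840179), stood at 189 ± 44.9 FPKM in WT and 120 ± 13.5 FPKM in cKO. The groups again did not overlap (log2 fold change -0.63, SE 0.193, limma adjusted p = 0.743), but the gap was narrow. WT replicate 1 stood at 138 FPKM, near the 132 of cKO replicate 1, and WT replicates 2 and 3 at 224 and 204.

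**Figure D1:**
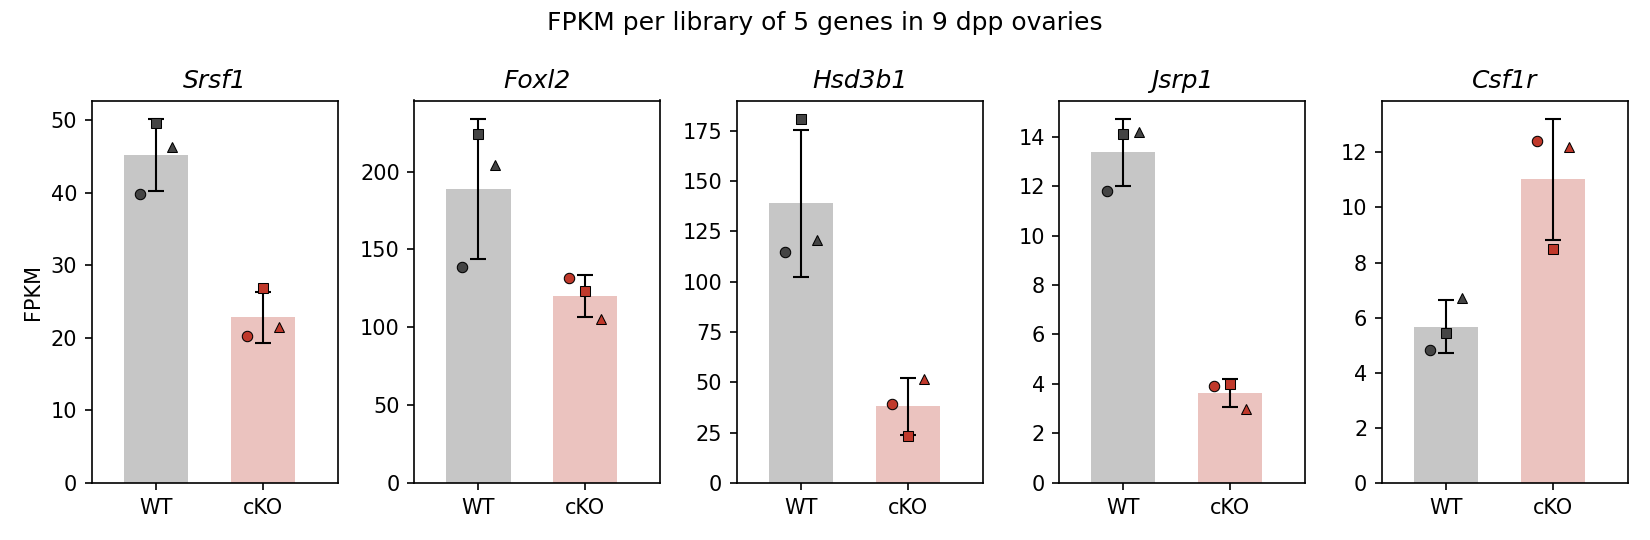
FPKM (vertical axis, linear from 0) of Srsf1, Foxl2, Hsd3b1, Jsrp1 and Csf1r in WT (grey) and cKO (red) ovaries; points are libraries (circle, square and triangle for replicates 1, 2 and 3), bars are means and error bars are SD (n = 3). Srsf1 had a mean of 45.3 FPKM in WT and 22.9 in cKO, and in each of the 5 genes the libraries of the groups did not overlap.

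Of the 14714 genes tested, 1 was higher and 2 were lower in cKO past the threshold. Jsrp1, which encodes a protein of the sarcoplasmic reticulum junction of muscle (chromosome 10, 80644330 to 80649359, minus strand), fell from 13.4 ± 1.35 FPKM in WT to 3.64 ± 0.564 FPKM in cKO (log2 fold change -1.64, SE 0.129, limma adjusted p = 0.0331). It lies next to the granulosa cell gene Amh (anti-Müllerian hormone, plus strand, 80641074 to 80643513), named for its position after its value was seen, which stood at 165 FPKM in WT and 126 FPKM in cKO. The other calls were pseudogenes, which like the genes they copy lie outside the rule for named genes and were chosen after their values were seen. Gm13736 (chromosome 2, 87356354 to 87357097), a copy of the signal recognition particle gene Srp9, fell by 2.43 on the log2 scale (SE 0.188, limma adjusted p = 0.0331). Srp9 itself stood at 25.9 ± 8.27 FPKM in WT and 47.3 ± 3.56 FPKM in cKO, so that the value of either gene is uncertain where reads of the copies are shared. Gm5900 (chromosome 7, 104598383 to 104599642), a copy of Lamtor3, rose from 0.193 ± 0.0756 to 2.93 ± 0.39 FPKM (log2 fold change 1.72, SE 0.15, limma adjusted p = 0.0437), on 3 to 78 recovered reads per library.

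These calls were not stable, although the log2 fold change of Jsrp1 stayed between -1.53 and -1.88 in all 21 other settings, those with a library left out included. Jsrp1 and Gm5900 lost theirs whichever single library was left out (Jsrp1, limma adjusted p = 0.0698 to 0.329; Gm5900, 0.0909 to 0.329), and Gm13736 kept its call only without WT replicate 2 (adjusted p = 0.0451, against 0.0734 to 0.216 otherwise). limma-voom on the recovered reads called 0 genes, with a smallest adjusted p of 0.109. At an unadjusted p under 0.05, limma found 933 genes (536 higher and 397 lower) and limma-voom 907, where chance gives 735.7 on average. Splits of the libraries that mix the genotypes gave 285 to 1239 by limma, with 958, 1125 and 1239 above the real count. The excess over 735.7 can therefore not be put down to genotype. In 1804 genes, 12.3% of those tested, the WT and cKO libraries did not overlap, where chance gives 10%.

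Among protein-coding genes with the smallest p-values, chosen after their values were seen, Plxna2, which encodes a semaphorin receptor, stood at 11.5 ± 0.91 FPKM in WT and 5.48 ± 0.654 in cKO (limma, adjusted p = 0.21). Cacna2d2, a calcium channel subunit, stood at 12 ± 1.13 and 6.51 ± 0.721 FPKM (adjusted p = 0.32). H1f2, a linker histone, stood at 19.5 ± 1.34 in WT and 37.6 ± 4.72 FPKM in cKO (adjusted p = 0.252), and the immunoglobulin receptor gene Fcgr2b at 4.22 ± 1.07 and 11.7 ± 2.29 FPKM (adjusted p = 0.345).

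Among the 28 gene lists tested, 8 were higher and 3 lower in cKO by camera at its preset correlation. None of the 11 passed with an estimated correlation (smallest adjusted p = 0.367) or by fry (smallest adjusted p = 0.0757). Each list call below was thus made only by camera in its preset setting.

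Granulosa cell genes were lower in cKO as a list, with 15 of 24 tested members lower and 9 higher (mean log2 fold change -0.18, SE 0.0684, camera adjusted p = 0.0215; adjusted p = 0.438 with an estimated correlation). Adjusted over the list alone, 1 member passed, and over all genes tested 0 did. That member, the homeobox gene Irx3, went the other way, from 23.2 ± 1.05 FPKM in WT to 35 ± 4.97 in cKO. The nuclear receptor gene Nr5a2 stood at 50.1 ± 6.23 and 32.3 ± 5.38 FPKM, and Kitl, which encodes the ligand of the oocyte receptor KIT, at 70.1 ± 4.02 and 50.6 ± 8.56 FPKM. The list's call was lost without WT replicate 1 (adjusted p = 0.101) and without cKO replicate 2 (adjusted p = 0.156). It held in 13 of 15 other settings and was lost with a filter at 5 FPKM and with library weights (highest adjusted p = 0.145).

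Macrophage and leukocyte genes formed the list with the smallest p. All 14 tested members were higher in cKO (mean log2 fold change 1.06, SE 0.34, camera adjusted p = 5.1e-12; adjusted p = 0.438 with an estimated correlation). Adjusted over the list alone, 10 members passed, all higher, and over all genes tested 0 did. Csf1r, the receptor for macrophage colony-stimulating factor, stood at 5.67 ± 0.958 FPKM in WT and 11 ± 2.2 in cKO. The complement genes C1qb and C1qc stood at 7.85 ± 1.42 and 6.64 ± 1.61 FPKM in WT against 22.9 ± 10.4 and 18.4 ± 8.07 in cKO, and the lysosomal glycoprotein gene Cd68 at 2.66 ± 0.753 against 5.94 ± 1.78. The list's score was 1.60, 0.55 and 1.02 in cKO replicates 1, 2 and 3.

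Interferon response genes were higher in cKO in all 15 members (mean log2 fold change 1.66, SE 0.842, camera adjusted p = 7.7e-10; adjusted p = 0.441 with an estimated correlation), with 0 members past the threshold adjusted over the list alone and 0 over all genes tested. The score was 3.27 in cKO replicate 1 against 0.43 and 1.27 in replicates 2 and 3, and without replicate 1 the mean log2 fold change was 0.85 (SE 0.419). Irf7, a regulator of the interferon response, stood at 70.2, 3.44 and 8.31 FPKM in cKO replicates 1, 2 and 3 and at 1.05, 1.22 and 1.65 FPKM in WT. The ubiquitin-like modifier gene Isg15 stood at 67.3, 5.44 and 6.27 FPKM in cKO and at 2.07, 0.655 and 1.72 FPKM in WT, and Ifit1 at 20.7, 1.64 and 6.94 against 0.176, 0.25 and 0.451 FPKM.

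Surface epithelium genes were higher in all 10 members, with scores of 0.33, 0.48 and 0.85 in cKO replicates 1, 2 and 3 and of 0.29, -0.11 and -0.17 in WT, so that WT replicate 1 lay close to cKO (mean log2 fold change 0.55, SE 0.212, camera adjusted p = 7.6e-06; adjusted p = 0.438 with an estimated correlation). Adjusted over the list alone, 1 member passed, and over all genes tested 0 did. It was the keratin gene Krt19, at 33.8 ± 2.4 FPKM in WT and 60.9 ± 7.57 in cKO. Aldh1a2, which encodes a retinoic acid synthesis enzyme, stood at 44.6 ± 5.31 and 71.2 ± 17.3 FPKM, and Krt7 at 6.27 ± 2.21 and 13.7 ± 5.68. Endothelial genes were higher in all 12 members by a small amount (mean log2 fold change 0.17, SE 0.0247, camera adjusted p = 0.00038; adjusted p = 0.367 with an estimated correlation), among them Cdh5 at 30.4 ± 0.949 and 34.4 ± 0.292 FPKM. Of the oviduct and ciliated epithelium genes, 6 of 7 were higher (mean log2 fold change 0.27, SE 0.196, camera adjusted p = 0.0215; adjusted p = 0.575 with an estimated correlation), including Epcam at 16.8 ± 2.41 and 25.7 ± 5.15 FPKM. Of the 11 genes on the oviduct list, Foxj1, Ovgp1, Dnah5 and Tekt1 lay below the filter. Only Epcam and Pax8 had an unadjusted limma p under 0.05, and Ccdc39 was lower. Ccdc39 and the genes below the filter are named after their values were seen. The oviduct call was lost without WT replicate 1, WT replicate 3 or cKO replicate 2 (adjusted p = 0.0518, 0.0556 and 0.424). Replicate 2 carried most of its size, with scores of 0.15, 0.65 and 0.01 in cKO replicates 1, 2 and 3. The call held in 12 of 14 other settings and was lost with no filter and with library weights (highest adjusted p = 0.145). In the endothelial and the oviduct list 0 members passed, adjusted over the list alone or over all genes tested.

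Targets of p53 were higher in 16 of 18 members (mean log2 fold change 0.27, SE 0.112, camera adjusted p = 0.00051; adjusted p = 0.438 with an estimated correlation). The score of WT replicate 1, 0.212, lay next to that of cKO replicate 3, 0.216, and away from the other WT libraries (-0.11 and -0.10). Of the 18 members, 4 had an unadjusted limma p under 0.05, all of them higher. Sesn2, a stress-induced metabolic regulator, stood at 4.37 ± 0.377 FPKM in WT and 5.93 ± 0.675 in cKO. Phlda3 stood at 12.8 ± 10.1 and 24 ± 1.65 FPKM, with WT replicate 1 at 24.4, inside the cKO range of 22.4 to 25.7. The death receptor gene Tnfrsf10b stood at 3.37 ± 0.211 and 4.23 ± 0.266 FPKM. As for the p53 targets, WT replicate 1 lay close to cKO in the next 2 lists, with scores of -0.11 for proliferation, inside the cKO range of -0.07 to -0.15, and -0.09 for cholesterol synthesis, next to the -0.11 of cKO replicate 3. Proliferation genes were lower in 21 of 23 members (mean log2 fold change -0.11, SE 0.0601, camera adjusted p = 0.003; adjusted p = 0.441 with an estimated correlation), with the mitotic checkpoint kinase gene Bub1b at 26.9 ± 1.34 and 22.5 ± 1.54 FPKM. Cholesterol synthesis genes were lower in 15 of 17 members (mean log2 fold change -0.13, SE 0.0457, camera adjusted p = 0.0016; adjusted p = 0.438 with an estimated correlation). In each of these 3 lists 0 members passed, adjusted over the list alone or over all genes tested. Apoptosis regulators, 13 of 19 higher, did not pass as a list (camera, adjusted p = 0.222).

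Mitochondrially encoded genes were higher in 11 of 12 members (mean log2 fold change 0.25, SE 0.165, camera adjusted p = 0.003; adjusted p = 0.575 with an estimated correlation) and ribosomal protein genes in 21 of 22 (mean log2 fold change 0.12, SE 0.119, camera adjusted p = 0.0327; adjusted p = 0.617 with an estimated correlation), with 0 members of either past the threshold, adjusted over the list alone or over all genes tested. The scores of the groups overlapped in both lists. Ribosomal scores were -0.01, -0.19 and 0.20 in WT and 0.17, 0.04 and 0.15 in cKO replicates 1, 2 and 3. The size of the ribosomal change thus depends on which WT library is counted, with WT replicate 2 lowest and WT replicate 3 highest of all. These scores and their order also depend on the list member Rps18, chosen after its values were seen. It ran from 32.2 to 472 FPKM within WT and from 33.4 to 812 FPKM within cKO. The mitochondrial call was lost without WT replicate 1, cKO replicate 2 or cKO replicate 3 (adjusted p = 0.1, 0.0664 and 0.113), and the ribosomal call without WT replicate 2, cKO replicate 2 or cKO replicate 3 (adjusted p = 0.859, 0.162 and 0.0685). Among 15 other settings, the mitochondrial call held in 13 and was lost with quantile normalization and library weights (highest adjusted p = 0.175). The ribosomal call held in 10 and was lost with a filter at 0.1 FPKM, no filter, quantile normalization, library weights and the replicate block (highest adjusted p = 0.884).

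**Figure D2:**
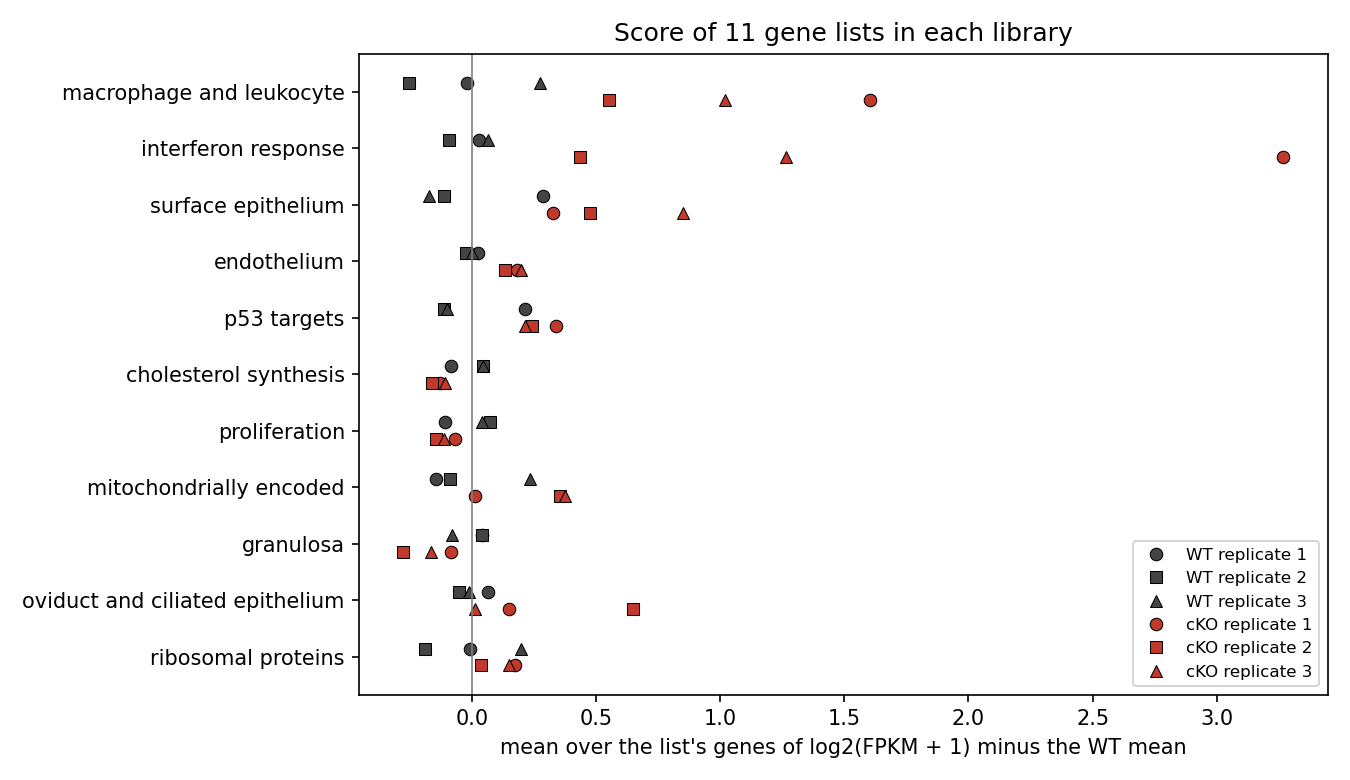
Score of the 11 gene lists past the camera threshold in each library (horizontal axis, mean over the list's genes of log2(FPKM + 1) minus the WT mean; grey for WT, red for cKO, symbols for replicates). cKO replicate 1 had the highest interferon score, 3.27, and the scores of the groups overlapped in the proliferation, mitochondrial, oviduct and ribosomal lists.

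Oocyte genes did not differ as a list, with 13 of 32 higher and 19 lower (mean log2 fold change -0.01, SE 0.0571, camera adjusted p = 0.9). Steroidogenic genes went both ways, 4 of 8 higher and 4 lower (camera, adjusted p = 0.392), but fry's test for change in either direction passed for this list (adjusted p = 0.00016). Hsd3b1, which encodes an enzyme of progesterone synthesis, was its 1 member past the threshold adjusted over the list alone and not over all genes tested. It stood at 139 ± 36.6 FPKM in WT and 38.1 ± 14.2 in cKO (log2 fold change -1.88, SE 0.301, limma adjusted p = 0.37). The other tested members had unadjusted limma p of 0.0953 or more, so fry's result need not reflect more than Hsd3b1. Cyp17a1, Cyp11a1, Lhcgr and Insl3 of this list, named after their values were seen, lay below the filter. The other SR protein genes (5 of 12 higher, camera adjusted p = 0.9) and the hnRNP genes (8 of 16 higher, camera adjusted p = 0.658) did not pass as lists, but each did without cKO replicate 2 (adjusted p = 0.0149 and 0.0264).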

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

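limma-voom on the recovered reads and the filter at 20 recovered reads were chosen after seeing the data. The log2 fold change of Srsf1 kept its direction and an unadjusted p under 0.05 in every alternative (-0.88 to -1.08). The count of genes higher in cKO went from 1 to 0 with a pseudocount of 0.1 or 0.5, no filter, a filter at 5 FPKM, rescaling to a common total, quantile normalization, protein-coding genes only and limma-voom, and to 3 with library weights. The count of genes lower went from 2 to 0 with no filter and limma-voom and to 1 with protein-coding genes only. Keeping protein-coding genes only drops the pseudogenes by construction. The filter at 5 FPKM likewise drops Gm5900, the gene called higher (mean 0.193 FPKM in WT and 2.93 in cKO). Elsewhere the cause was not tested. Leaving out a single library gave 0 to 1 genes higher and 0 to 1 lower, and 8 to 13 lists past the threshold against 11. The similar gene counts hide a change of genes. Without cKO replicate 1 the call was Snord100, without replicate 2 Tpm3-rs7, and without replicate 3 Rpl34-ps1 and Gm8730. Each time 0 of the main calls were kept. These genes are named after their values were seen. Lists past the threshold numbered 0 with an estimated correlation, 0 by fry, and 9 to 12 elsewhere. Among the called lists the estimated correlation ran from -0.012 (endothelial) to 0.936 (interferon). The endothelial value lay below the preset 0.01, yet the list's unadjusted camera p rose from 5.4e-05 to 0.0131. A high correlation thus does not account for each lost call.

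The values gave no sign that the replicate numbers pair the libraries. Same-numbered libraries had correlations of deviations of 0.18, -0.08 and -0.06, where differently numbered ones ran from -0.23 to 0.23. So few libraries cannot exclude a pairing. With the replicate number as a block, 0 genes were higher and 0 lower, and 10 lists passed.

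Some uncalled lists changed direction, the cause not tested. With library weights these were the oocyte, stromal and erythroid lists (adjusted p = 0.469, 0.487 and 0.832). With single libraries left out these were the oocyte, stromal, erythroid, SR protein, hnRNP and immediate early lists. Where the direction changed, camera adjusted p was 0.308 (SR protein, without cKO replicate 3) or more. Over all runs with a library left out, adjusted p ranged from 0.336 to 0.941 for oocyte and 0.0388 to 0.532 for stromal genes. It ranged from 0.00434 to 0.564 for erythroid and 0.0149 to 0.858 for SR protein genes. For hnRNP genes it ranged from 0.0264 to 0.99 and for immediate early genes from 0.00158 to 0.991. The lowest value of each range came from a run that kept the direction. With single libraries left out, the log2 fold change of Rps18 ranged from -0.79 to 1.74 and that of Lamtor3 from -0.10 to 0.023. That of Sox17 ranged from -0.00258 to 0.568 and that of Hbb-bs from -0.25 to 0.73.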

Other observations

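Several lists not described above did not pass by camera: pregranulosa and Wnt genes (adjusted p = 0.209), hedgehog targets (0.214), smooth muscle and pericyte genes (0.209), Sertoli and male pathway genes (0.112), BMP and TGF-beta signalling (0.18), hypoxia and glycolysis (0.255), basement membrane (0.112), stromal mesenchyme (0.38), erythroid genes (0.214), immediate early genes (0.18), YAP and TEAD targets (0.204) and the unfolded protein and integrated stress response (0.208). Some passed with a single library left out: smooth muscle without cKO replicate 2 (adjusted p = 9.7e-05), erythroid and stromal without cKO replicate 1 (0.00434 and 0.0462), stromal and basement membrane without WT replicate 3 (0.0388 and 0.0139), immediate early and YAP without WT replicate 2 (0.00158 and 0.0044), and the stress response without cKO replicate 3 (0.0407). In 1 other setting each, smooth muscle and immediate early genes passed with library weights (adjusted p = 0.0041 and 0.00901), basement membrane with quantile normalization (0.0294) and Sertoli genes with rescaling to a common total (0.049). The adipocyte and skeletal muscle lists, with 1 and 2 members above the filter, were not tested. The pregranulosa genes went both ways, 9 higher and 7 lower, with 0 past the threshold adjusted over the list alone. Of them, Krt8 and Krt18 stood at 24.3 ± 4.02 and 19.9 ± 2.78 FPKM in WT against 40.2 ± 12.4 and 35 ± 10.8 in cKO (limma adjusted p = 0.76 and 0.74). The glomerular-type collagen gene Col4a4 stood at 16.3 ± 0.576 against 11.6 ± 3.08 FPKM (limma adjusted p = 0.768). The BMP receptor gene Bmpr1b stood at 6.81 ± 1.23 against 4.67 ± 0.487 FPKM (limma adjusted p = 0.743).

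Tests chosen only after the result was seen are those of the leukocyte and interferon lists without cKO replicate 1, of leukocyte against globin genes, of leukocyte against oocyte genes, and of the genes near Srsf1 with Srsf1 itself left out. The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3 genes past the threshold, and 3 of the 10 splits, the real split included, gave as many, with 9 as the highest of the others. That highest count came from setting WT replicate 1 and cKO replicates 1 and 3 against the rest, so differences among these samples other than genotype can give counts above the real one. The first principal component (31.9% of the variance) ran mainly from cKO replicate 1 (26.1) to cKO replicate 2 (-32.4). The second component (27.9%) separated the genotypes, with 8.27, 28.8 and 10.1 in WT and -19.8, -22.6 and -4.68 in cKO. Within cKO, replicate 2 stood apart, with a chi-square per degree of freedom of 36.4 and 36.7 against replicates 1 and 3, where those differed from each other by 17.6 and WT libraries by 15.6 to 19.2. For gene lists the real split gave 11 and was the 1 split with a count as large. The other splits, which mix the genotypes, still gave 5 to 10. Camera at its preset correlation thus passed many lists whatever the grouping.

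Leukocyte and interferon genes were higher together in cKO, most in replicate 1. The leukocyte genes had a mean log2 fold change of 0.79 (SE 0.28) without cKO replicate 1, above a limit of 0.2 by little more than 2 SE. That limit was set after the scores were seen, and the SE rests on few libraries, so passing it decides little. The leukocyte scores of 0.55 and 1.02 in cKO replicates 2 and 3 both lay above WT (-0.25 to 0.27). That list was thus not high in replicate 1 alone. For the interferon genes the mean log2 fold change without cKO replicate 1 was 0.85 (SE 0.419). Their scores of 0.43 and 1.27 in cKO replicates 2 and 3 both lay above WT (-0.09 to 0.07), so this list was not high in replicate 1 alone. These 2 interferon scores differ too much for their mean to pass the limit of 0.2 by 2 SE. Blood left in the tissue stays open, since the leukocyte genes exceeded the 4 globin genes by 0.47 (SE 0.721) in mean log2 fold change, but the erythroid score was lowest (-0.31) in cKO replicate 1, where the leukocyte score was highest, and the abundant Hbb-bs stood there at 68.7 FPKM against 84.1, 65.1 and 127 in WT, which goes against blood in that library, while replicates 2 and 3 had erythroid scores of 0.26 and 1.19 and the scarce Hba-a2 stood at 3.57, 8.5 and 16.3 FPKM in cKO against 2.48, 2.25 and 2.02 in WT. More immune cells in cKO ovaries, or an infection or immune response in single animals, may account for the pattern and were not tested.

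The leukocyte, surface epithelium and endothelial lists were higher as lists and the granulosa list lower, though 9 of its 24 members were higher and its call was lost without WT replicate 1 or cKO replicate 2 (adjusted p = 0.101 and 0.156). A lower share of granulosa cells alone would raise the markers of all other cell types alike. The leukocyte list exceeded the oocyte list by 1.07 (SE 0.308) in mean log2 fold change. These lists were set against each other after their values were seen. At most, the difference shows that such a lower share would not by itself account for the leukocyte rise. That rise has open explanations of its own, so the test cannot decide for the smaller shifts of the other lists. Oviduct tissue carried along with the ovary cannot be told apart for the epithelial genes, because surface epithelium genes exceeded the oviduct genes Pax8, Ovgp1, Foxj1 and Sox17 by only 0.22 (SE 0.385). Of these 4 genes, Ovgp1 and Foxj1 lay below the filter, and the log2 fold change of Sox17, singled out after its values were seen, was -0.00258 without cKO replicate 2, so the comparison is a weak one. An effect of the knockout on granulosa cells themselves may add to the pattern and was not tested separately.

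Both called pseudogenes lie away from Srsf1, with 0 called genes on chromosome 11, so a stretch of chromosome inherited along with the targeted Srsf1 allele does not account for them. Such a stretch may account for other genes: of 25 genes with p under 0.001 besides Srsf1, 3 (Gm11545, Gm20234 and Prr15l, named after their values were seen) lie within 10 Mb of it among 229 tested there (Fisher's exact test, two-sided, p = 0.00665), although direct effects of the knockout stay open. Chromosome 11 as a whole held 7 of the 25, with 7.97% of the tested genes. Krt19, the member of the surface epithelium list named above, was among these 7 but lies beyond 10 Mb. The other splits had 0 or 1 genes near Srsf1 among totals of 3 to 41. They do not tell how rare the real share near Srsf1 is, since 1 of them had 1 of only 3. Reads moving between copies cannot be told apart for Gm13736, which fell by 381 scaled reads (SE 70.6) while the other members of its family gained 545 (SE 133), more than it lost by 164 (SE 78.8). For Gm5900, which gained 63.4 scaled reads, Lamtor3 differed by -27.1 (SE 40.8), a spread too wide to decide.

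The ribosomal protein gene Rps18, chosen after its values were seen, stood at 32.2, 317 and 472 FPKM in the WT libraries and at 812, 33.4 and 401 FPKM in the cKO libraries.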
